A study of Mus musculus with 4 samples.

How the data were processed

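RNA was sequenced from mouse cardiac fibroblasts, isolated from hearts at postnatal days 1 to 3, that carried the reprogramming factors Mef2c, Gata4 and Tbx5 (MGT) together with a short hairpin RNA. The MGT+shNT group received a non-targeting hairpin and the MGT+shScd1 group a hairpin against Scd1, and both were collected at day 7 of reprogramming, when the cells are called induced cardiomyocyte-like cells (iCM). Each group held 2 libraries, as the titles and treatment labels state. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was depleted, and stranded libraries were sequenced as read pairs on a HiSeq X instrument. The labels name the molecule as polyA RNA while the protocol describes ribosomal RNA depletion, and the files do not settle which was used.

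The authors deposited 1 table of 56691 genes with raw read counts per gene and library, whole numbers that were neither normalised nor pooled, per the file headers and the values. The table also held FPKM values deposited by the authors, and these equalled the FPKM computed from the count, the table's exonic gene length and the library's total count for 100.0% of the values, within the rounding of the deposited value (0.005). The submitters' processing notes name Trimmomatic 0.36, Subread 1.5.1, featureCounts, SAMtools and the genome build mm10. The aligner, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here, so genes with near-identical copies and overlapping genes are uncertain. The deposited coordinates were compared with GENCODE M21, an annotation of the GRCm38 (mm10) assembly. Of the gene identifiers, 52073 (91.9%) were found there, and of 52036 nuclear genes on the same chromosome in both, 2.78% had the same start while 96.8% had the same width. The deposited coordinates were therefore not used, and positions are given in GRCm38 from GENCODE M21.

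Total counts were 20894972 and 15135227 in MGT+shNT replicates 1 and 2 and 19104319 and 18679918 in MGT+shScd1 replicates 1 and 2. In the tests, a gene entered where filterByExpr kept it (minimum count 10, minimum total count 15), which left 16234 genes. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM normalisation factors of 0.989, 0.946, 1.03 and 1.03 and the group as the single term, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05 with no fold minimum, and "rose" and "fell" are used of called genes. Log2 fold changes are MGT+shScd1 over MGT+shNT and are followed by their standard error (SE) where it is given, and levels are CPM, counts scaled to the TMM-adjusted library size, as mean ± SD of the 2 libraries. The common biological coefficient of variation was 0.067 with 10.9 prior degrees of freedom. Where a group held at most 3 counts of a gene, its ratio is given with an exact 95% counting interval, which covers counting error only.

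The 2 libraries of each group were compared before they were averaged. A chi-square test of their counts gave 43.6 per degree of freedom in MGT+shNT (5.23 without the 10 genes that contributed most) and 2.82 in MGT+shScd1 (2.63 likewise), so neither pair agreed within sampling noise and all 4 libraries were counted. Nothing in the labels says that the replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. On counts simulated from the real means and library sizes for this comparison, with 200 of the 16234 genes changed, the same test recovered 38% of 50 genes changed 1.25-fold, 62% of 50 changed 1.5-fold, 80% of 50 changed 2-fold and 90% of 50 changed 4-fold, and 21 of 156 calls (13.5%) were unchanged genes. With a log2 shift of 0.4 put into 1 list of the simulated data, 2 of 26 lists were called, that list among them.

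A set of 27 gene lists (877 genes) was fixed before the data were examined, as were the main test, the rule for named genes and the alternatives, except where a choice is said to have been made later. The lists are sarcomere, calcium handling and ion channels, cardiac regulators and hormones, fibroblast and extracellular matrix, smooth muscle and myofibroblast, nuclear-encoded and mitochondrially encoded oxidative phosphorylation, tricarboxylic acid cycle and pyruvate oxidation, fatty acid oxidation, PGC-1alpha axis and mitochondrial biogenesis, glycolysis, fatty acid synthesis and desaturation, cholesterol synthesis, unfolded protein and integrated stress response, cell cycle, interferon response, inflammatory cytokines, Wnt target genes, p53 targets and cell death, oxidative stress response, and the markers of macrophages, endothelial cells, epicardial and mesothelial cells, neural and Schwann cells, erythroid cells, adipocytes and skeletal muscle. They were written from general knowledge and not from these samples. Each list was tested with camera in limma 3.58.1, which compares its members with all other tested genes, at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 26 lists that had tested members. Members were also counted with p-values adjusted over the list alone.

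The genes named were Scd1, Mef2c, Gata4, Tbx5 and Ppargc1a; the 10 largest rises and the 10 largest falls by log2 fold change among called genes with an assigned symbol, a mean of at least 1 FPKM in the higher group and no overlap between the libraries of the groups; and, for each list, the up to 4 tested members with the smallest unadjusted p. In all 122 genes met the rule, and some of them are not reported here. Other genes named were chosen after their values were seen.

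The alternatives were the replicate number as a block, each library left out in turn, no filter on low counts, a stricter filter (at least 5 FPKM in at least 2 libraries), DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with genes of at least 1 FPKM in at least 2 libraries, a model without mitochondrially encoded genes, a log2 fold change minimum of 1, camera with the correlation estimated per list, the rotation test fry, and lists without shared members. Alternatives added after seeing the data were protein-coding genes alone, an offset that removed the trend of each library on gene length (lowess span 0.3), camera on log2 CPM, counts of list members without MGT+shNT replicate 2, and a model without genes that hold the words ACCCAAA or AACCCAA in the 3' UTR. Also after seeing the data, Gene Ontology and KEGG terms of 15 to 500 tested genes were tested with camera, and 7-base words of 3' UTRs from GENCODE M21 were tested by regression of the log2 fold change on the presence of each word, with UTR length, mRNA length, mean CPM and dinucleotide shares as covariates and Benjamini-Hochberg adjustment over words held by at least 20 genes. Word searches and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The hairpin sequences were not used here.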

Results

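The data were 4 RNA-seq libraries of mouse cardiac fibroblasts in reprogramming towards induced cardiomyocyte-like cells (iCM) with Mef2c, Gata4 and Tbx5 (MGT), 2 with a non-targeting hairpin (MGT+shNT) and 2 with a hairpin against Scd1 (MGT+shScd1), all at day 7. Scd1 encodes stearoyl-CoA desaturase, the enzyme that makes monounsaturated fatty acids from saturated ones. Total counts ranged from 15135227 to 20894972 per library, and between 24759 and 25231 genes had at least 1 count. MGT+shNT replicate 2 stood apart in its ribosomal RNA: Rn18s-rs5 took 3.32% of its counts, against 0.199% in the other MGT+shNT library and 0.141% and 0.129% in the MGT+shScd1 libraries. Lars2, whose locus holds a repeat resembling ribosomal RNA, took 0.329% of its counts and between 0.0132% and 0.0171% in the other 3 libraries. The nuclear RNA Malat1 likewise took 0.541% there, against 0.157% to 0.173% elsewhere.

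The comparison asked how reprogramming cells with Scd1 knocked down differed at day 7 from cells with the non-targeting hairpin. Scd1 itself fell by 3.34 on the log2 scale. Beside it, Ppargc1a, the gene of the coactivator PGC-1alpha, and many sarcomere, glycolysis and nuclear-encoded oxidative phosphorylation genes were higher in MGT+shScd1 cells. Many macrophage markers, fibroblast matrix genes and epicardial and mesothelial markers were lower. Of 16234 genes tested, 2122 rose and 2641 fell.

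Scd1 (ENSMUSG00000037071, minus strand of chromosome 19, 44394455 to 44407879 in GRCm38) had 84.4 and 63.5 CPM in the MGT+shNT libraries and 6.64 and 8.04 CPM in the MGT+shScd1 libraries. Its mean went from 73.9 ± 14.8 to 7.34 ± 0.996 CPM (SD, n = 2 each), a log2 fold change of -3.34 (SE 0.14) and an adjusted p of 4.31e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the source of all adjusted p-values of single genes here. The knockdown target was thus lower in both libraries labelled MGT+shScd1. Another desaturase gene, Scd2, chosen after its values were seen, had a log2 fold change of -0.15 and did not pass (adjusted p = 0.469). Ppargc1a (ENSMUSG00000029167, minus strand of chromosome 5, 51454250 to 51567726) rose from 3.26 ± 1.32 to 14.6 ± 0.868 CPM, with 48 and 60 counts in MGT+shNT and 277 and 294 in MGT+shScd1, a log2 fold change of 2.22 (SE 0.21, adjusted p = 5.03e-06).

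All 3 reprogramming factors fell. Tbx5 (ENSMUSG00000018263, plus strand of chromosome 5, 119832668 to 119885219) went from 1083 ± 60.6 to 812 ± 21.7 CPM, a log2 fold change of -0.42 (SE 0.06, adjusted p = 0.000249). Gata4 (ENSMUSG00000021944, minus strand of chromosome 14, 63198922 to 63271692) went from 684 ± 32.4 to 526 ± 24.8 CPM, a log2 fold change of -0.38 (SE 0.06, adjusted p = 0.000584). Mef2c (ENSMUSG00000005583, plus strand of chromosome 13, 83504034 to 83667080) went from 688 ± 60.7 to 521 ± 66.5 CPM, a log2 fold change of -0.40 (SE 0.09, adjusted p = 0.00296). The Mef2c call was lost without MGT+shScd1 replicate 1 (log2 fold change -0.28, adjusted p = 0.108), with the DESeq2 Wald test (adjusted p = 0.0579) and on the log2(FPKM + 1) scale (adjusted p = 0.115). Counts per gene do not separate introduced from endogenous copies of these genes.

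**Figure D1:**
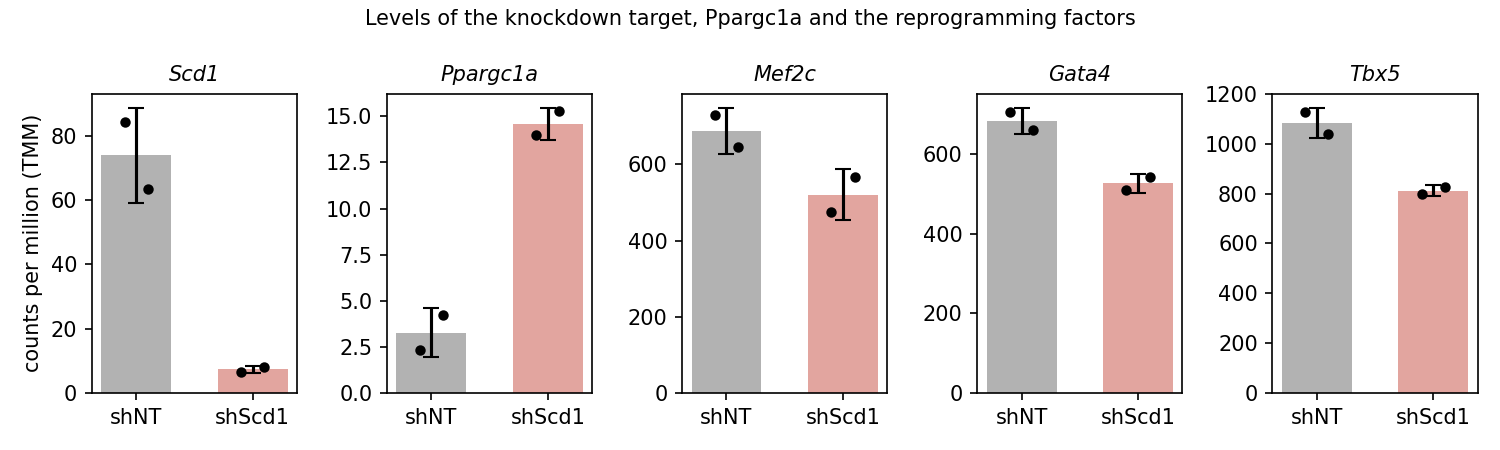
Level of Scd1, Ppargc1a, Mef2c, Gata4 and Tbx5 in TMM-scaled CPM (vertical axis, from 0) in MGT+shNT (grey) and MGT+shScd1 (red) libraries; points are the 2 libraries of each group, bars their mean and error bars the SD. Scd1 was lower and Ppargc1a higher in both MGT+shScd1 libraries, and the 3 factors were lower in MGT+shScd1, with means of 812 against 1083 for Tbx5.

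Among genes with a symbol, a mean of at least 1 FPKM in the higher group and no overlap between the groups, the largest rise was that of Mmp10, a stromelysin that degrades matrix (log2 fold change 4.71, SE 0.24, from 0.501 to 13.6 CPM). Other large rises were those of the histone gene H2bu2, which had 1 count in the MGT+shNT libraries and 30 in the MGT+shScd1 libraries (ratio 26.9, exact 95% counting interval 4.46 to 1096), the urotensin receptor Uts2r (4.02), the carotene oxygenase Bco1 (3.93), the G protein subunit Gna14 (3.90), Prss35 (3.05), Itih5 (7.98-fold), Mybpc2, a myosin-binding protein of fast skeletal muscle (2.90), and Stk32b (2.79). The largest falls were Atp6v0d2, a proton pump subunit of osteoclasts and macrophages (log2 fold change -4.61, SE 0.24), Spp1, which encodes osteopontin (-4.53, SE 0.08, from 184 ± 5.75 to 7.95 ± 0.209 CPM), the fatty acid binding protein Fabp4 (-4.41), the macrophage elastase Mmp12 (-4.14), Tlr8 (-4.09), Mmp3 (-3.96), the fatty acid transporter Cd36 (-3.94, from 62.5 ± 5.55 to 4.04 ± 1.45 CPM), Rn18s-rs5 (-3.83), the chemokine Ccl3 (-3.77) and Lars2 (-3.77). Adjusted p-values of these genes lay between 1.13e-12 (Spp1) and 0.00406 (Lars2). With each library left out in turn, the log2 fold change ranged from 2.51 to 4.09 for Itih5, 3.11 to 5.49 for Uts2r, 3.32 to 4.54 for Gna14, 3.82 to 6.79 for H2bu2, -4.48 to -3.04 for Mmp3 and -5.11 to -3.93 for Fabp4. The calls on Rn18s-rs5 and Lars2 were lost without either MGT+shScd1 library (adjusted p from 0.0834 to 0.108) and on both FPKM scales (adjusted p from 0.173 to 0.217). The Lars2 call was also lost with the DESeq2 Wald test (adjusted p = 0.0791) and limma-voom (adjusted p = 0.0644). Without MGT+shNT replicate 2 the log2 fold change of Rn18s-rs5 was -0.62 and that of Lars2 -0.37, so both were still lower, by less. Malat1, chosen after its values were seen, had a log2 fold change of -1.18 with all libraries (adjusted p = 0.0257) and 0.02 without that library.

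Of the 4763 called genes (29.3% of those tested), 502 rose and 428 fell with an absolute log2 fold change of at least 1, and the median absolute log2 fold change of called genes was 0.48. When MGT+shNT replicate 2 was left out, 5395 genes were called (2450 higher, 2945 lower). Without MGT+shScd1 replicate 1 or 2, 2272 and 2559 genes were called. On log2(FPKM + 1), where the test, the filter and the scale all differed, 63.5% of 3214 calls were higher against 44.6% of the 4763. The deposited FPKM were scaled to total counts and carried no TMM factors. The median of all genes lay at 0.07 there, against 0.0001 in the main test, so levels on that scale were shifted upward as a whole.

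Of the 26 lists with tested members, camera called 4 higher and 3 lower at the preset correlation and 0 with the correlation estimated per list.

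Sarcomere genes, which encode the contractile apparatus of striated muscle, were the list with the smallest camera p among those that were higher. Of 46 tested, 27 rose, 7 fell and 12 did not pass, or 27 and 8 adjusted over the list alone (median log2 fold change 0.39, camera adjusted p = 3.47e-16, and adjusted p = 0.64 with an estimated correlation). Csrp3, a Z-disc protein, rose by 2.55 (27.3 ± 5.19 to 158 ± 6.96 CPM), troponin C (Tnnc1) by 2.44 (19.1 ± 3.04 to 102 ± 1.36 CPM), alpha-actinin 2 (Actn2) by 1.52 and Synpo2l by 1.36. Among members chosen after their values were seen, the alpha myosin heavy chain Myh6 rose (1.31), as did Actc1 (1.10), while troponin T (Tnnt2, -0.36), the atrial light chains Myl4 (-0.27) and Myl7 (-0.31) and the ventricular light chain Myl2 (-2.34, from 1.73 ± 0.323 to 0.33 ± 0.393 CPM, with 12 and 1 counts in MGT+shScd1) fell. With MGT+shNT replicate 2 left out, 29 rose and 7 fell, and without MGT+shScd1 replicates 1 and 2, 20 and 18 rose and 3 and 0 fell. Skeletal muscle markers moved the same way. Of 25 members, 10 passed the filter on low counts. Of these 10, 6 rose, 1 fell and 3 did not pass the test, or 7 and 1 adjusted over the list alone (median 0.98, camera adjusted p = 0.000656, and adjusted p = 0.64 with an estimated correlation). With no filter on low counts, 23 members were tested, 6 rose, 1 fell and the median was 0.17. The median of 0.98 thus holds for the members that passed the filter and not for the whole list. The embryonic myosin heavy chain Myh3 rose by 4.29 from 0.202 to 4.06 CPM, Mylpf by 2.37 (1.96 to 3.18 with 1 library left out), Tnnt1 by 2.36 and the perinatal myosin Myh8 by 0.79. The same 6 and 1 were counted without MGT+shNT replicate 2.

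Ion channel and cardiac regulator genes went both ways. Of 46 genes of calcium handling and ion channels, 8 rose, 13 fell and 25 did not pass, or 9 and 15 adjusted over the list alone. The median was -0.09, the mean 0.08 and the camera direction up (adjusted p = 0.641). The calsequestrin Casq1 (2.12) and Popdc3 (1.51) rose, and the atrial potassium channel Kcnj5 fell (-0.99, from 219 ± 9.34 to 110 ± 1.15 CPM). This list had 5 and 5 rises and 8 and 9 falls without MGT+shScd1 replicates 1 and 2. Among 29 cardiac regulators and hormones, 4 rose, 7 fell and 18 did not pass, or 4 and 8 adjusted over the list alone (median -0.05, adjusted p = 0.696). The sinoatrial regulator Shox2 rose (1.71), and the atrial natriuretic peptide gene Nppa (-1.35, from 51.9 ± 5.05 to 20.2 ± 1.9 CPM), Tbx20 (-0.58) and Mef2d (-0.60) fell. Nkx2-5, chosen after its values were seen, fell by 1.87 from 1.14 CPM.

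**Figure D2:**
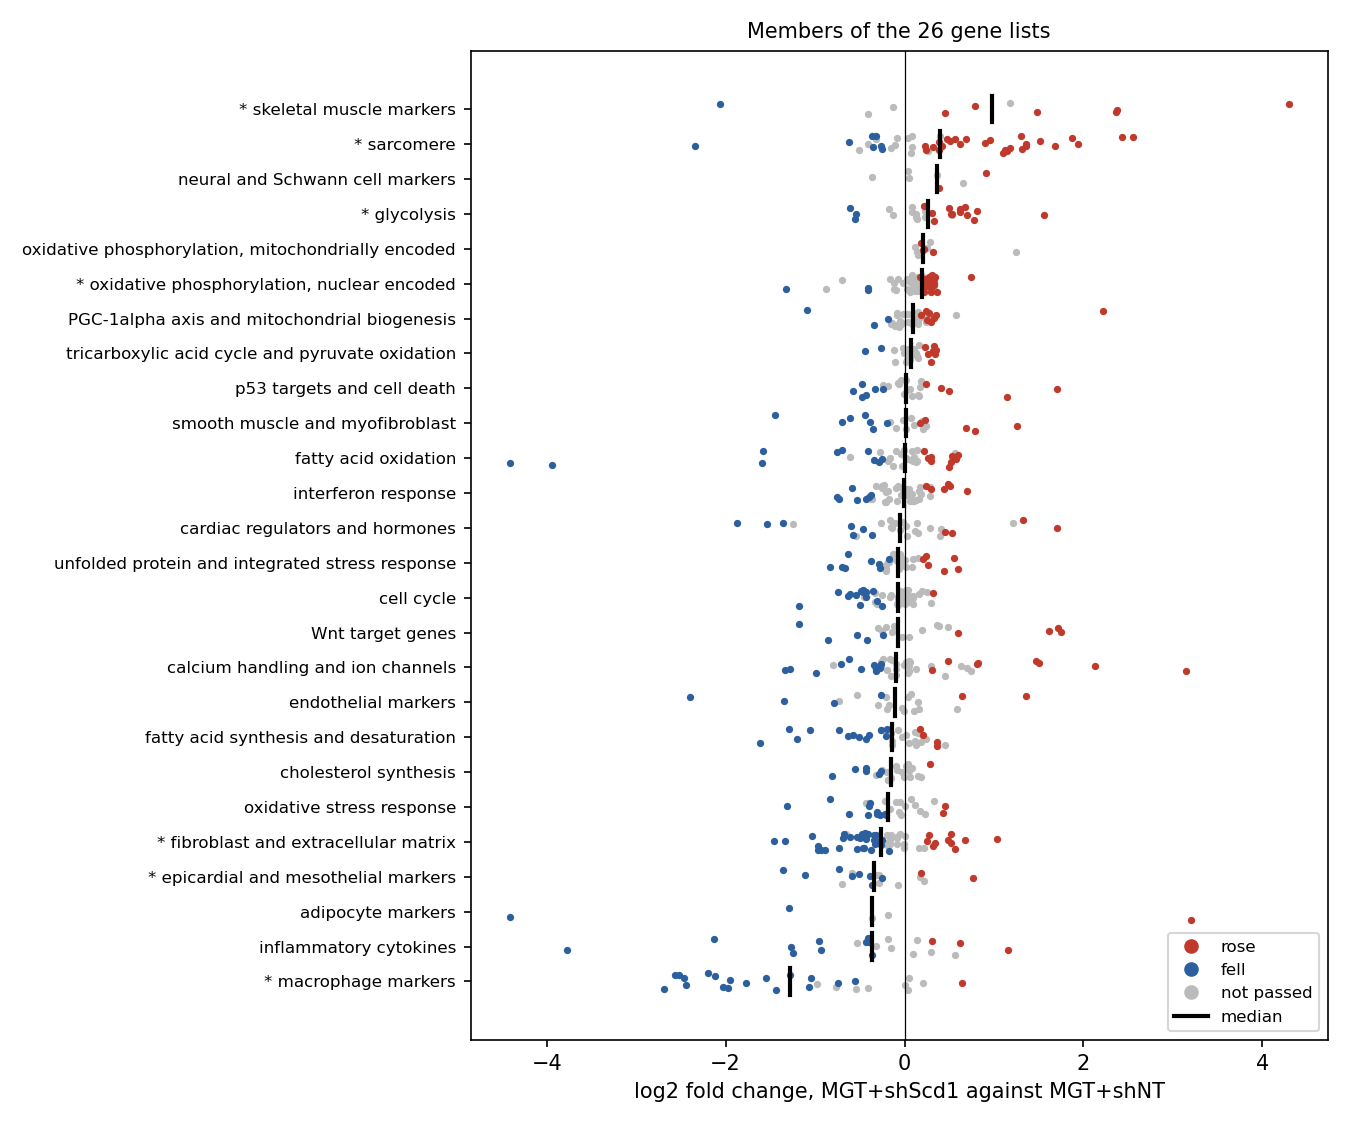
Log2 fold change, MGT+shScd1 against MGT+shNT (horizontal axis), of each tested member of the 26 lists, ordered by the list's median (black line); red points rose, blue points fell and grey points did not pass, and a star marks lists called by camera at the preset correlation. Skeletal muscle (median 0.98 over the 10 tested of 25 members) and sarcomere (0.39) lie at the top and macrophage markers (-1.28) at the bottom.

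The list of nuclear-encoded oxidative phosphorylation genes was called higher at the preset correlation, though most members did not pass. Of 80 tested, 25 rose, 3 fell and 52 did not pass, or 34 and 3 adjusted over the list alone (median 0.20, camera adjusted p = 0.000729, and adjusted p = 0.727 with an estimated correlation). The complex III subunits Uqcr10 (0.74) and Uqcrc1 (0.33) and the ATP synthase subunit Atp5b (0.36, from 642 ± 10.1 to 824 ± 16.4 CPM) rose, and another complex III subunit, Uqcrb, fell by 1.32 (44.6 ± 2.56 to 17.8 ± 0.601 CPM). Without MGT+shNT replicate 2, 31 rose and 3 fell, and without MGT+shScd1 replicates 1 and 2 the rises numbered 5 and 14 with adjusted camera p-values of 0.0237 and 1.97e-05. Of 11 mitochondrially encoded members, 4 rose, 0 fell and 7 did not pass, or 6 and 0 adjusted over the list alone (median 0.21, camera adjusted p = 0.0993). These were mt-Nd6 (0.32), mt-Nd1 (0.22), mt-Nd5 (0.21) and mt-Cytb (0.18). Without MGT+shNT replicate 2, 9 rose, against 1 and 0 without MGT+shScd1 replicates 1 and 2. With the replicate number as a block, mt-Nd5 (adjusted p = 0.0548) and mt-Cytb (adjusted p = 0.101) did not pass, and with the gene length offset none of the 4 did (adjusted p from 0.0506 to 0.126). Counts of mt-Nd4l, mt-Atp6, mt-Co3 and mt-Co2 were low, with 0.425, 8.56, 9.85 and 17.9 CPM in MGT+shNT against 8118 CPM of mt-Co1, and are uncertain, since nuclear copies of these genes can share their reads.

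In the PGC-1alpha and mitochondrial biogenesis list, which includes Ppargc1a, 8 of 42 rose, 3 fell and 31 did not pass, or 8 and 3 adjusted over the list alone (median 0.09, camera adjusted p = 0.128), among them the prohibitin Phb2 (0.36) and the import receptor Tomm22 (0.33), which rose, and the adenine nucleotide carrier Slc25a5 (-0.34, lost on log2(FPKM + 1) at an adjusted p of 0.0642), which fell, as did the nuclear receptor Ppara (-1.10), chosen after its value was seen. Without MGT+shScd1 replicate 1, 1 rose and 1 fell, and Phb2 (adjusted p = 0.0508) and Tomm22 (adjusted p = 0.0598) did not pass. The mitochondrial transcription factor Tfam (-0.09, adjusted p = 0.534) and the coactivator Ppargc1b (-0.05, adjusted p = 0.895), chosen after their values were seen, did not pass. In the tricarboxylic acid cycle and pyruvate oxidation list, 7 of 26 rose, 2 fell and 17 did not pass, the same 7 and 2 adjusted over the list alone (median 0.07, camera adjusted p = 0.121). The isocitrate dehydrogenase genes Idh3b (0.35), Idh3a (0.33) and Idh2 (0.30) rose and the pyruvate dehydrogenase subunit Dlat fell (-0.44). Here too 1 rose and 1 fell without MGT+shScd1 replicate 1, and Idh3a (adjusted p = 0.0633) and Idh2 (adjusted p = 0.0856) did not pass. Of 26 glycolysis genes, 13 rose, 3 fell and 10 did not pass, or 15 and 3 adjusted over the list alone (median 0.27, camera adjusted p = 2.98e-05, and adjusted p = 0.64 with an estimated correlation). The lactate exporter Slc16a3 (1.56), Pfkl (0.78), Tpi1 (0.70) and Eno1 (0.67, from 280 ± 9.26 to 445 ± 12.4 CPM) were among the rises, and without MGT+shNT replicate 2 the counts were 12 and 3.

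Lipid genes were mixed. In fatty acid oxidation, 9 of 38 rose, 10 fell and 19 did not pass, or 9 and 11 adjusted over the list alone, and the median of 0.00 differed from the mean of -0.28 and the downward camera test (adjusted p = 0.0737). Hadha, the alpha subunit of the mitochondrial trifunctional protein, fell by 1.59 (159 ± 1.46 to 52.8 ± 0.215 CPM), while the gene of its beta subunit, Hadhb, chosen after its values were seen, had a log2 fold change of -0.01 (adjusted p = 0.959). Cd36, Fabp4 and the pyruvate dehydrogenase kinase Pdk4 (-1.58) also fell. Of 35 genes of fatty acid synthesis and desaturation, 4 rose, 13 fell and 18 did not pass, or 5 and 14 adjusted over the list alone (median -0.14, camera adjusted p = 0.105), with falls of Cebpa (-1.29), Lpin2 (-0.73), Fads3 (-0.63) and Acly (-0.43). In cholesterol synthesis, 1 of 25 rose, 6 fell and 18 did not pass, or 1 and 8 adjusted over the list alone (median -0.15, camera adjusted p = 0.105). Stard4 (-0.81) and Insig1 (-0.55) fell. Leaving out MGT+shScd1 replicate 1 or 2 gave 3 and 5 rises and 6 and 7 falls in fatty acid oxidation. It gave 0 and 0 rises and 5 and 6 falls in fatty acid synthesis. Cholesterol synthesis had 3 and 3 falls there and 10 falls without MGT+shNT replicate 2.

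Fibroblast and extracellular matrix genes were called lower as a list at the preset correlation. Of 56 tested, 10 rose, 29 fell and 17 did not pass, or 10 and 32 adjusted over the list alone (median -0.26, camera adjusted p = 8.74e-05, and adjusted p = 0.64 with an estimated correlation). The growth factor receptor Pdgfrb fell by 1.46 (495 ± 22.4 to 179 ± 10.8 CPM), Fbln1 by 1.34, Col1a2 by 1.03 (4291 ± 117 to 2103 ± 22.8 CPM) and Col6a2 by 0.97, whereas periostin (Postn, 1.03) and Tnc (0.56), chosen after their values were seen, rose. The counts were 10 and 32 without MGT+shNT replicate 2, 7 and 22 without MGT+shScd1 replicate 1 and 6 and 20 without MGT+shScd1 replicate 2. Of 21 smooth muscle and myofibroblast genes, 5 rose, 7 fell and 9 did not pass, the same adjusted over the list alone, and the median (0.01) and the upward camera test (adjusted p = 0.636) differed in sign from the mean (-0.02). Mcam (1.26) and desmin (Des, 0.68) rose, and Cald1 (-0.70) and Mylk (-0.61) fell. The rises numbered 9 without MGT+shNT replicate 2 and 3 with each other library left out.

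Markers of macrophages, another cell type that a heart cell preparation can hold, were also called lower at the preset correlation. Of 27 tested, 1 rose, 18 fell and 8 did not pass, the same adjusted over the list alone (median -1.28, camera adjusted p = 3.47e-16, and adjusted p = 0.64 with an estimated correlation). Lysozyme (Lyz2) fell by 2.20 (560 ± 10.8 to 122 ± 5.7 CPM), Cd68 by 2.47, Ms4a7 by 2.45 and Ctss by 1.54, and the member that rose was the complement gene C1qb (0.65, from 3.68 CPM), named after its value was seen. Without MGT+shNT replicate 2, 0 rose and 22 fell (median -1.48), and without MGT+shNT replicate 1, 3 rose and 14 fell (median -0.63). Inflammatory cytokine genes went the same way in part: of 21, 3 rose, 10 fell and 8 did not pass, the same adjusted over the list alone (median -0.37, camera adjusted p = 0.0737). Vcam1 (-0.95), C3 (-1.27) and Cxcl12 (-0.40) fell and the prostaglandin synthase Ptgs2 rose (1.16). In the interferon response list, 6 of 49 rose, 7 fell and 36 did not pass, the same adjusted over the list alone (median -0.01, camera adjusted p = 0.915), with rises of Ifi27 (0.51) and Bst2 (0.45) and falls of Ifi204 (-0.59) and Ifi203 (-0.75, lost on both FPKM scales at an adjusted p of 0.0723). That result rested on which MGT+shNT library was used: without replicate 2, 6 rose and 22 fell (camera down, adjusted p = 0.00868), and without replicate 1, 17 rose and 4 fell (camera up, adjusted p = 0.0275).

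Epicardial and mesothelial markers were called lower as a list at the preset correlation. Of 18 tested, 2 rose, 8 fell and 8 did not pass, or 3 and 9 adjusted over the list alone (median -0.34, camera adjusted p = 0.00609, and adjusted p = 0.64 with an estimated correlation), with Efemp1 at -1.35, Krt18 at -1.11, mesothelin (Msln) at -0.73 and Aldh1a2 at -0.51. Without MGT+shNT replicate 2, 3 rose and 9 fell, without MGT+shScd1 replicates 1 and 2 the rises numbered 1 and 0 and the falls 5 and 7, and the list was not called under the stricter filter (adjusted p = 0.107). Of 20 endothelial markers, 2 rose, 4 fell and 14 did not pass, the same adjusted over the list alone, and the median (-0.10) and mean (-0.19) were below 0 while camera pointed up (adjusted p = 0.636). Aqp1 (1.36) and Flt1 (0.64) rose, and Vwf (-2.40, from 2.55 CPM) and Eng (-0.26) fell. The falls numbered 2 and 1 without MGT+shScd1 replicates 1 and 2. The Eng call was lost without replicate 2 (adjusted p = 0.0989) and on both FPKM scales (adjusted p = 0.112). In the neural and Schwann cell list, 2 of 7 rose, 0 fell and 5 did not pass, the same adjusted over the list alone (median 0.36, camera adjusted p = 0.139). Uchl1 rose by 0.91 and Tubb3 by 0.39. The Tubb3 call was lost without MGT+shScd1 replicate 1 (adjusted p = 0.104) or 2 (adjusted p = 0.053). Of 5 adipocyte markers, 1 rose, 2 fell and 2 did not pass, or 1 and 3 adjusted over the list alone (median -0.36, camera adjusted p = 0.0737), with Car3 higher (9.2-fold, from 4 counts in the MGT+shNT libraries, and log2 fold changes of 2.87 to 3.86 with 1 library left out) and Fabp4 and Cebpa lower. No erythroid marker passed the filter, and the globin gene Hba-a1 had 7, 0, 0 and 1 counts in the libraries.

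Growth and stress lists were not called by camera. Of 51 cell cycle genes, 1 rose, 15 fell and 35 did not pass, or 1 and 16 adjusted over the list alone (median -0.07, camera adjusted p = 0.0599), with falls of cyclin D1 (Ccnd1, -1.17, from 129 ± 5.87 to 57.1 ± 1.27 CPM), Cenpa (-0.54), Mcm4 (-0.49) and Mki67 (-0.45). In the p53 and cell death list, 5 of 25 rose, 6 fell and 14 did not pass, or 7 and 6 adjusted over the list alone (median 0.01, camera adjusted p = 0.443). The cell cycle inhibitors Cdkn2a (1.70) and Cdkn2b (1.14) and the kinase Plk2 (0.49) rose and Cdkn1a fell (-0.33). Of 20 Wnt target genes, 4 rose, 5 fell and 11 did not pass, or 4 and 6 adjusted over the list alone, and the mean (0.14) differed in sign from the median (-0.07) and the downward camera test (adjusted p = 0.696). Axin2 (1.61) and Myc (0.60) rose and Nkd1 (-0.41) fell. In the unfolded protein and integrated stress response list, 6 of 36 rose, 8 fell and 22 did not pass, or 6 and 10 adjusted over the list alone (median -0.07, camera adjusted p = 0.337), with Edem1 (-0.70) and Herpud1 (-0.66) lower and Ddit4 (0.55) and Sesn2 (0.44) higher. Of 26 oxidative stress genes, 2 rose, 11 fell and 13 did not pass, or 4 and 11 adjusted over the list alone (median -0.19, camera adjusted p = 0.105), among them the extracellular superoxide dismutase Sod3 (-1.31), Srxn1 (-0.62) and Txn1 (-0.40), which fell, and the ferritin light chain Ftl1 (0.43), which rose. These counts were lower without MGT+shScd1 replicates 1 and 2, with 8 and 8 falls in the cell cycle list and 4 and 5 in oxidative stress. Falls numbered 2 and 6 in the unfolded protein response, where 2 and 3 rose, 3 and 2 in p53, where 3 and 4 rose, and 3 and 2 among Wnt targets, where 2 and 2 rose.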

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

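The settings of protein-coding genes alone, the gene length offset, camera on log2 CPM, list counts without MGT+shNT replicate 2 and the model without 3' UTR word genes were chosen only after the results were seen. With 2 libraries per group, p-values rest on a spread pooled across genes, and where 1 library is left out the lone sample of its group is assumed to vary like the other group. Scd1, Ppargc1a, Gata4 and Tbx5 kept their direction and their side of the threshold under every setting in which they were tested. Over all settings, named genes kept both in 1834 comparisons, lost the call in 45 and gained it in 2, and list tests kept both in 454 comparisons, with 14 weaker, 53 stronger and 23 reversed in direction. Of the 23 reversals, 1 passed the threshold, that of the interferon list below. No called gene changed sign, except 4 without MGT+shNT replicate 2. At depths of 15135227 to 20894972 counts, 38% of the 50 genes with the smallest simulated change were recovered, so small changes in list members that did not pass were not shown to be absent. Where a value differed and no reason is given, the cause was not tested.

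No sign of a pairing of the libraries by replicate number was seen. The deviations of same-numbered libraries from their group means had a correlation of 0.01 over 16234 genes, which does not exclude a shared culture or day. With the replicate number as a block, 4990 genes were called (2253 higher, 2737 lower) against 4763, and besides mt-Nd5 (adjusted p = 0.0548) and mt-Cytb (adjusted p = 0.101) no other call on a named gene or list changed.

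Each library left out in turn gave between 2272 and 5395 called genes, 897 to 2450 higher and 1375 to 2945 lower, with the lowest counts without MGT+shScd1 replicate 1 and the highest without MGT+shNT replicate 2. The Mef2c log2 fold change ranged from -0.54 to -0.28. Adjusted camera p-values ranged from 0.291 to 0.927 for calcium handling (pointing down without MGT+shNT replicate 1, 0.723), 0.159 to 0.664 for smooth muscle (down without MGT+shNT replicate 1), 0.0122 to 0.123 for mitochondrially encoded oxidative phosphorylation, 0.0237 to 0.114 for fatty acid oxidation, 0.0189 to 0.373 for fatty acid synthesis, 0.0145 to 0.291 for cell cycle, 0.00653 to 0.138 for inflammatory cytokines and 0.00868 to 0.244 for interferon response. The interferon list was called down without MGT+shNT replicate 2, called up without MGT+shNT replicate 1 (0.0275) and pointed up without MGT+shScd1 replicate 2 (0.244).

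The stricter filter, which tested 7779 genes, called 3155 (1701 lower). There the regulators (0.875) and interferon (0.678) lists pointed up, endothelial markers were called up (0.0449) and epicardial markers were not called (0.107). A log2 fold change minimum of 1 left 930 genes, 502 higher and 428 lower. With no filter, lists newly called were mitochondrially encoded oxidative phosphorylation (0.0172), tricarboxylic acid cycle (0.0387) and PGC-1alpha axis (0.0437), up, and fatty acid oxidation (0.0131), cholesterol synthesis (0.0378), cell cycle (0.00569), inflammatory cytokines (0.0437) and oxidative stress (0.0272), down.

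The DESeq2 Wald test called 1369 genes higher, put Mef2c at -0.40 without a call, called mitochondrially encoded oxidative phosphorylation (0.0114) and inflammatory cytokines (0.0314), and turned interferon up (0.82). Under limma-voom, mitochondrially encoded oxidative phosphorylation (0.00102) and cell cycle (0.0484) were called, and calcium handling (0.73) and endothelial markers (0.922) pointed down. On log2(FPKM + 0.1), 3154 genes were called and 1157 were lower, and on log2(FPKM + 1) 1173 were lower. Neither FPKM scale carried TMM factors, so the median of all genes was shifted upward on both (0.09 and 0.07). Mef2c was at -0.31 and -0.30 on these scales without a call. Their list p-values, in that order, were 0.00183 and 0.00196 for mitochondrially encoded oxidative phosphorylation, 0.0102 and 0.0104 for the tricarboxylic acid cycle, 0.0415 and 0.0407 for the PGC-1alpha axis, 0.0426 and 0.042 for cell cycle and 0.015 and 0.012 for adipocyte markers, all newly called, and 0.925 and 0.949 for calcium handling and 0.962 and 0.949 for endothelial markers, both pointing down.

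With the correlation estimated per list, the 7 called lists had adjusted p-values of 0.64 (sarcomere, fibroblast, glycolysis, macrophage, epicardial, skeletal muscle) and 0.727 (nuclear-encoded oxidative phosphorylation). The directional fry test kept glycolysis (0.0163) and gave 0.0834 for sarcomere, 0.0768 for fibroblast and for skeletal muscle, 0.132 for nuclear-encoded oxidative phosphorylation and 0.0894 for macrophage and epicardial markers. Its mixed form, which asks for change in either direction, newly called calcium handling, regulators, fatty acid oxidation, p53 targets and endothelial markers (each 0.00126), smooth muscle (0.00216), unfolded protein response (0.00178), cell cycle (0.00238), cholesterol synthesis (0.00358), fatty acid synthesis and Wnt targets (each 0.00636), adipocyte markers (0.00875), oxidative stress (0.0097), the PGC-1alpha axis (0.0112), the tricarboxylic acid cycle (0.0128), mitochondrially encoded oxidative phosphorylation (0.0131), inflammatory cytokines (0.0272) and neural markers (0.0335). Without shared members, Wnt targets (0.556) and adipocyte markers (0.628) pointed up.

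With camera on log2 CPM, mitochondrially encoded oxidative phosphorylation (0.0104) and cell cycle (0.0216) were called, and calcium handling (0.591), smooth muscle (0.849) and endothelial markers (0.805) pointed down. With protein-coding genes alone, interferon pointed up (0.87). Without the 3' UTR word genes, which left 14226 genes tested and 3669 called, cell cycle (0.0349), oxidative stress (0.0475) and adipocyte markers (0.0423) were called down, and regulators (0.854), fatty acid oxidation (0.854), interferon (0.957) and Wnt targets (0.46) pointed up. DESeq2 size factors, the model without mitochondrially encoded genes and the gene length offset changed no list call. Under the offset mt-Nd6, mt-Nd5, mt-Nd1 and mt-Cytb lost their calls (adjusted p from 0.0506 to 0.126).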

Other observations

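The term tests, the tests of macrophage, oxidative phosphorylation and sarcomere genes, and those of Hadha and Uqcrb without MGT+shNT replicate 2, of shared 3' UTR ends and of the order of sites were chosen only after the result was seen, whereas the other tests of words and matches were written before they were run, the last 2 of them once the word was known. Gene Ontology and KEGG terms were tested beside the fixed lists. Of 862 Gene Ontology terms, 6 were higher and 12 lower in MGT+shScd1 by camera, and of 328 KEGG terms 5 were higher and 26 lower, with 0 called in either collection when the correlation was estimated. Cell-matrix adhesion was lower, with 24 of 48 genes fallen and 4 risen (adjusted p = 1.18e-06). So were JAK-STAT signalling (45 of 102 fell and 8 rose, adjusted p = 0.000177), osteoclast differentiation (45 of 108 fell and 7 rose, adjusted p = 0.000177) and the triglyceride metabolic process (8 of 19 fell and 0 rose, adjusted p = 0.00278). These terms were not tested without the macrophage markers, of which 18 of 27 fell, so whether they are separate from that fall is not known. Cytoplasmic translation was higher, with 33 of 158 genes risen and 1 fallen (adjusted p = 0.036). Over all tested genes, the 1624 with the shortest exonic length had a median log2 fold change of 0.08 and the 1624 with the longest -0.04.

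Genes with a short word in the 3' UTR were lower in MGT+shScd1. Among 13380 genes, counting 1 per shared UTR end, the 1364 that held ACCCAAA had a shift of -0.22 on the log2 scale (SE 0.02) and the 1260 that held AACCCAA one of -0.20 (adjusted p = 3.15e-25), after adjustment for UTR length, mRNA length, level and dinucleotides. Of 16372 words, 18 went with lower and 25 with higher levels, and 14 of the 18 held AACCCA or ACCCAA, and CGCATTA was among those that went with higher levels (125 genes, 0.32, adjusted p = 2.87e-06). Of 516 genes in which both words overlapped in 1 site, 46.9% fell and 8.72% rose, against 33.4% and 9.38% of 1492 genes with another 7-base form, 23.0% and 13.0% of 1425 with ACCCAA alone and 14.6% and 15.6% of 9947 with none. Camera gave p = 3.99e-12 for the overlapping site (p = 0.0436 with an estimated correlation), p = 7.45e-07 for the 7-base forms (p = 0.0389 likewise) and p = 0.157 for ACCCAA alone. The site classes were built from the words that ranked first among the 16372 on these same fold changes. These camera p-values do not allow for that choice and are no separate evidence. Scd1 itself holds AACCCAA in its 3' UTR, with the core at base 4322 of a 4832-base mRNA, but neither ACCCAAA nor the overlapping site. Of the 16372 words, 3938 lie somewhere in that mRNA, so a shared word can arise by chance. Among all 13411 genes searched, 9 of the 19 words that went with lower levels lie there, though such words overlap and are not separate. Among genes named by the rule and reported here, Scd1, Gata4, Cd36, Atp6v0d2, Mmp12 and Pdgfrb held at least 1 of the words and fell. So did Fbln1, Col1a2, Ccnd1, Hadha, Uqcrb, Pdk4, Tbx20, Col6a2, Cald1, Dlat, Slc25a5, Fads3, Stard4, Edem1, Cxcl12 and Cdkn1a. In the other direction, H2bu2, Uts2r, Prss35, Slc16a3 and Flt1 held at least 1 and rose.

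Macrophage markers were lower with a median of -1.28, though Lyz2, at 122 CPM, was still well counted. The ribosomal RNA of MGT+shNT replicate 2 did not account for this, since without that library the list had an adjusted camera p of 5.08e-27. That p-value assumes that the lone MGT+shNT library varies like the MGT+shScd1 pair, so the effect size is the safer guide. The list's median was -1.48 without that library and -0.63 without MGT+shNT replicate 1. The members did not share a single factor of change: 7 of 27 (C1qb, C1qa, Laptm5, Aif1, Spi1, Adgre1 and Lcp1) had 95% intervals wholly above the list's median, and Cochran's Q was 729.8 on 26 degrees of freedom. This cannot decide against a uniform loss of macrophages, since members made in part by other cells would then fall unequally. A uniform loss of macrophages, a change in their state or the loss of a subset of them may account for the fall, and each stays open as a hypothesis. Whether Scd1 loss or another effect of the hairpin set it off was not tested, as only 1 hairpin group was compared.

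Nuclear-encoded oxidative phosphorylation and sarcomere genes were higher with medians of 0.20 and 0.39, and the first was 0.13, with 5 of 80 genes risen, without MGT+shScd1 replicate 1. Gene length did not account for either, since 0 of 10000 random lists matched on length and level had a median at or above either, and 95% of them lay between -0.04 and 0.09 and between -0.10 and 0.11. Nor did MGT+shNT replicate 2, without which the adjusted camera p was 0.000305 and 4.21e-21. Those p-values likewise assume that the lone MGT+shNT library varies like the MGT+shScd1 pair. The medians without that library were 0.21 for oxidative phosphorylation and 0.52 for sarcomere genes. The rise of Ppargc1a, a known driver of mitochondrial genes, is a candidate explanation for the first, but of its list of 42 genes 8 rose, and no perturbation of Ppargc1a was compared. A larger share of reprogrammed cells, or a later stage of them, is a hypothesis for the second that was not tested. Cardiac genes went both ways: 27 of 46 sarcomere genes rose and 7 fell, while of 29 cardiac regulators and hormones 4 rose and 7 fell. Nppa (-1.35) and Tbx20 (-0.58) were among those falls.

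Hadha and Uqcrb fell apart from Hadhb and Uqcr10, and a test set down beforehand, that both 3' UTRs share a word of the Scd1 mRNA that goes with lower levels, was not met (0 of 4 shared words), while their longest exact match to that mRNA was 14 bases, under the 15 set for a long match, and without MGT+shNT replicate 2 both were still lower (adjusted p of at most 1.42e-28). These p-values without MGT+shNT replicate 2 do not measure variation among MGT+shNT samples, since the spread came from the MGT+shScd1 pair. The log2 fold changes in that fit were -1.60 for Hadha and -1.27 for Uqcrb, against -1.59 and -1.32 with all libraries. Keeping 1 gene per shared UTR end left all 1364 genes with ACCCAAA in place (adjusted p = 9.55e-32 by the word regression). Identical UTR ends thus did not make the shift, while UTRs that are only nearly alike were not tested. Base composition was argued against, since genes with the overlapping site in the 3' UTR were shifted by -0.21 (SE 0.04) relative to those with it in the coding sequence. So was the library MGT+shNT replicate 2, without which the median difference between genes with the overlapping site and with none was -0.28. The order of the means, not adjusted for UTR or gene length, ran from 0.03 with no site through -0.05 and -0.17 to -0.25 with the overlapping site. Pairing of the Scd1 hairpin with other 3' UTRs could give this order, a hypothesis found and tested on the same data. Scd1 holds AACCCAA but not ACCCAAA, which does not decide this hypothesis without the hairpin sequence. The 3' UTRs of Hadha and Uqcrb both hold ACCCAAA. Their shared-word test could not count it, since that test admitted only words of the Scd1 mRNA. Its unmet result therefore cannot decide whether pairing lowered Hadha and Uqcrb. A microRNA of the cells with the same seed was not tested, the hairpin sequence was not used here, and hairpin and knockdown cannot be told apart in this design for Hadha and Uqcrb. Without the genes that hold either word, Ppargc1a (2.20) and the 7 lists called at the preset correlation were still called. These calls thus did not rest on genes that hold a word themselves. Indirect effects of pairing on other genes would remain in that model, so it cannot decide whether pairing contributed to these calls.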
